A study of Mus musculus with 8 samples.

How the data were processed

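ATAC-seq libraries were made from amygdala neurons of 8 male mice, 4 with a guide against Rosa26 (sgRosa) and 4 with a guide against Nr2f2 (sgNr2f2), and sequenced with paired ends, per the labels' protocols. Neurons had been isolated with a magnetic adult neuron kit. The labels describe 4 mice per group, so each library was taken as 1 animal. The groups and replicate numbers came from the sample titles.

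The deposited files were 1 narrowPeak list per library in mm10 coordinates. The submitters' processing notes name fastp 0.23.2, FastQC 0.11.9, MultiQC 1.11, Picard, MACS2 2.2.9.1, DiffBind 3.10.0 and HOMER 4.10. The aligner, the treatment of duplicate fragments, the shift of Tn5 cut sites and the peak calling options were not given in the sources used here. Peaks were called per library and not on pooled libraries, as each list has its own positions. Each deposited line gives the authors' integer score, the fold enrichment at the summit as a ratio over background, and the −log10 p and −log10 q from the peak caller. The score and fold are the peak's own values, not scaled between libraries, and were used only to rank, filter or describe peaks within a list. No deposited −log10 p was below 2.00, so the lists reach down to a p of 0.01, and no peak was narrower than 150 bp.

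Peaks on chromosomes 1 to 19 and X were kept, and several summits of 1 interval were collapsed to the strongest, which removed 3499 lines over the 8 libraries. No peaks were excluded for lying in repeats or at sites of excess signal. Number, covered length, width, fold enrichment, q, the recovered background and X chromosome values were taken from the full lists. Other comparisons, unless said otherwise, used the strongest 53864 peaks of each library by −log10 p. Overlapping intervals (at least 1 bp) of the 8 lists were merged into regions. Regions present in all 8 lists were ranked within each library, converted to normal scores and compared with limma 3.58.1 (R 4.3.3) with a trend and Benjamini-Hochberg adjustment. Group means were compared by two-sided exact permutation over all 70 assignments, whose smallest p is 0.0286. The similarity of libraries was compared over the 35 splits into 4 and 4, one-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

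Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21631 protein-coding genes on these chromosomes. The table holds no strand, so what had been planned as promoters was measured at either end of a protein-coding gene, within 1 kb, and the nearest start site as the nearest end. No genome sequence was used here, and the planned comparison of motifs in distal peaks was not run. The 24 gene lists, the group comparisons and, except where said below, the alternatives were fixed before the data were examined. Text names Nr2f2 and Nr2f1, up to 4 members per list with the largest difference in number of detecting libraries, up to 10 regions and gene ends per direction found in every library of 1 group and none of the other, and shared regions past the threshold. With fewer than 5 such gene ends in a direction, those found in 4 libraries against 1 or in 3 against 0 fill the names up to 10. Some list members that this rule selects are not reported here. Any other named item is said to have been picked after its values were seen.

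Depth per library is unknown. The fold and −log10 p of each peak were solved for a whole pileup and a background, taking fold as (pileup + 1) / (background + 1) and p as a Poisson tail. At least 99.9% of peaks in every library solved to a whole pileup between 2 and 299 within a relative tolerance of 1e-04. The most frequent background was taken as the genome-wide one and gives depth only relative to the other libraries, as fragment length and genome size were not given in the sources used here.

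The calculations were tested on simulated lists made by moving the real lists apart. Of 40 planted regions per group, 38 and 39 were recovered as exclusive among 415658 regions, with 0 false ones. These regions were planted at a −log10 p above that of every real exclusive region reported below. Each library was moved by its own offset, so that only planted regions would be shared. The counts therefore show neither the recovery of weak regions nor how often exclusive regions arise by chance. In limma over 230 regions with planted shifts in both directions, 10 of 10 shifts of 4 within-group SDs and 4 of 10 of 2 SDs were called, with 0 false calls among 14. With shifts in 1 direction, 15 of 15 of 4 SDs and 4 of 15 of 2 SDs were called and 5 of the 24 calls were false, because raising some ranks lowers others. All simulated regions had 1 common spread, whereas the spread of real shared regions differs between regions. These rates therefore do not give the recovery among the real shared regions. A planted gene list gained the smallest p of 0.0286 but an adjusted p of 0.343 over the 24 lists.

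Alternatives were each replicate left out, a replicate block, full lists, peaks with −log10 q of at least 5, lists of 26932 peaks, order by fold enrichment, an overlap of 50%, 500 bp summit windows, absence from the full lists, a 2 kb window, limma without trend or with robust variances, percentiles in place of normal scores, the nearest gene end, and a 200 kb flank. Camera, also planned, gave no value, as no list held 2 or more shared regions. As a control for position, peaks were moved sideways in steps of 20 kb up to 200 kb in both directions. That control and the relation of peak number to the chance of exceeding the smallest passing pileup were chosen after seeing the data. The same holds for the density within 1 Mb of list genes and the lists without their member with the most peaks. The analysis without sgRosa 4 and sgNr2f2 2, and the background without each replicate, were also chosen after seeing the data. So were the tests of the threshold step, depth, knockdown, gene table and weak peaks, with their ratios by rank of peak, and the counts of splits for exclusive regions and gene ends.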

Results

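The data are ATAC-seq peak lists, which record where the transposase Tn5 cut chromatin more often than in the surrounding genome, from neurons isolated from the amygdala of male C57BL/6J mice. Virus carrying a guide RNA was delivered to the amygdala, and the mice were later restrained in tubes on 7 days, fear conditioned on 1 day and given extinction training on 3 days. The guide was directed either at the Rosa26 locus, the control (sgRosa, n = 4 libraries), or at Nr2f2 (sgNr2f2, n = 4 libraries). Nr2f2 encodes the orphan nuclear receptor COUP-TFII, a DNA-binding transcription factor. Chromosomes 1 to 19 and X carried 63648, 62348, 60880 and 143405 peaks in sgRosa libraries 1 to 4, and 103939, 97620, 63213 and 53864 peaks in sgNr2f2 libraries 1 to 4. Read depth is unknown, since the lists hold no read totals. The background of fragments per position recovered from the peak values lay between 2.304 in sgRosa 4 and 4.284 in sgRosa 3. Numbers of peaks, covered length, width, fold enrichment, q, the recovered background and X chromosome values come from the full lists. Other values, unless said otherwise, come from the 53864 strongest peaks of each library, the length of the shortest list.

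The targeted gene was examined first. Nr2f2 (gene ID 11819) lies on chromosome 7 at 70351946 to 70366746 in mm10. In the lists of equal length, the gene body held 1 peak in sgRosa 3, at 70363786 to 70363935, and 1 peak in sgRosa 4, at 70362684 to 70362842, and no peak in the other 6 libraries. The full lists added 1 peak in the gene body in sgRosa 4, at 70355798 to 70355947, and 1 in sgNr2f2 1, at 70365953 to 70366102. Of these 4 peaks, the one in sgNr2f2 1 was within 1 kb of an end of the gene. Within 50 kb of Nr2f2 there were 1, 2, 7 and 1 peaks in sgRosa libraries 1 to 4 and 2, 2, 1 and 2 peaks in sgNr2f2 libraries 1 to 4. The means were 2.75 ± 2.87 (SD, n = 4) and 1.75 ± 0.5 (SD, n = 4), with a two-sided exact permutation p of 0.971. The related receptor gene Nr2f1 (gene ID 13865; chromosome 13, 78188971 to 78198873) had 1.5 ± 1.29 peaks within 50 kb in sgRosa and 2.5 ± 1.29 in sgNr2f2 (SD, n = 4 each; exact p = 0.457). A peak in or near a gene does not measure its transcript or protein, so these values do not check the knockdown. Without sgRosa 3 the difference at Nr2f2 changed sign, to 0.417 more peaks in sgNr2f2.

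The first comparison asked whether the number, covered length and width of the listed peaks differed between the groups. The number of peaks averaged 82570 ± 40572 in sgRosa and 79659 ± 24819 in sgNr2f2 (SD, n = 4 each; exact p = 0.8). The peaks covered 15.4 ± 7.55 Mb and 14.9 ± 4.76 Mb (SD, n = 4 each; exact p = 0.8286), with a mean peak width of 186 ± 1.91 bp and 186 ± 2.10 bp. The median peak width was 166.5 ± 1.91 bp in sgRosa and 168 ± 2.16 bp in sgNr2f2 (SD, n = 4 each; exact p = 0.457). All of these differences were smaller than the spread between replicates. The difference in number (sgNr2f2 minus sgRosa) was -2911 peaks and turned to 17367 without sgRosa 4, which had the most peaks, 2571 without sgNr2f2 3 and 5687 without sgNr2f2 4. The difference in covered length, -0.484 Mb, turned to 3.29, 0.577 and 1.15 Mb without the same libraries. Few peaks were strong: between 4.81% and 18.6% of a list had a q under 0.05, and between 220 and 312 peaks per library had a −log10 q of at least 5. Number and covered length therefore describe lists of mostly weak peaks and do not measure the extent of accessible chromatin.

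The number of peaks was set against the recovered background over the 8 libraries. Pearson's r was -0.674 (permutation p = 0.059, adjusted p = 0.059) and Spearman's rho was -0.405 (permutation p = 0.327, adjusted p = 0.327). Leaving out sgRosa 2 and sgRosa 4, the libraries farthest from the median background, gave an r of -0.327. Leaving out 1 library gave an r of -0.791 (permutation p = 0.0315) without sgRosa 2, -0.797 (p = 0.0444) without sgNr2f2 1, -0.744 (p = 0.0452) without sgNr2f2 4 and -0.117 (p = 0.737) without sgRosa 4, so the relation rests on sgRosa 4. After the data were seen, the number was set against the chance that a position at background exceeds the smallest pileup among the listed peaks. This gave an r of 0.952 (permutation p = 4.5e-04, adjusted p = 8.9e-04) and a rho of 0.786 (permutation p = 0.0279, adjusted p = 0.0559). Without sgRosa 4 and sgNr2f2 1 this r was 0.915. These were the 2 relations computed in this family.

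**Figure D1:**
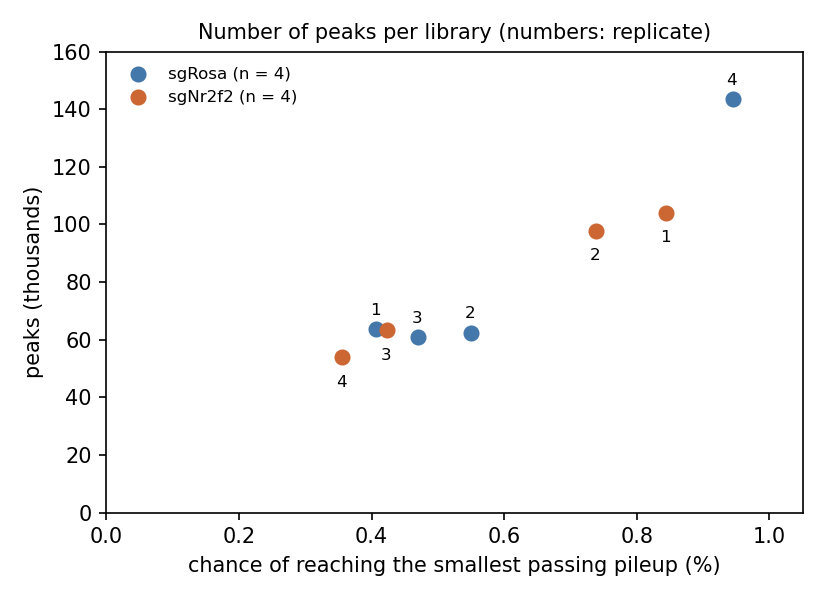
Each point is 1 library, with its number of peaks on the y axis. The x axis, labelled as reaching, gives the percent chance that a position at that library's background exceeds the smallest pileup among its peaks. The 143405 peaks of sgRosa 4 stood at the highest chance, 0.944%, and the 53864 of sgNr2f2 4 at the lowest, 0.356%.

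The position of peaks relative to genes was measured at both ends of 21631 protein-coding genes, because the gene table gives no strand. Of the equal-length lists, 3.75 ± 0.312% of peaks in sgRosa and 3.81 ± 0.498% in sgNr2f2 had their summit within 1 kb of a gene end (SD, n = 4 each; exact p = 0.743). The difference, 0.0617 percentage points, turned to -0.0942 without sgRosa 4 and -0.0823 without sgNr2f2 3. Moved sideways by 20 to 200 kb, on average 2.67% to 3.68% of a library's peaks lay at gene ends. The observed share was 1.27 ± 0.16 times the moved share in sgRosa and 1.12 ± 0.0545 times in sgNr2f2 (SD, n = 4 each; exact p = 0.143). Every library exceeded all of its 20 moved shares, from a ratio of 1.04 in sgNr2f2 2 to 1.46 in sgRosa 1.

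**Figure D2:**
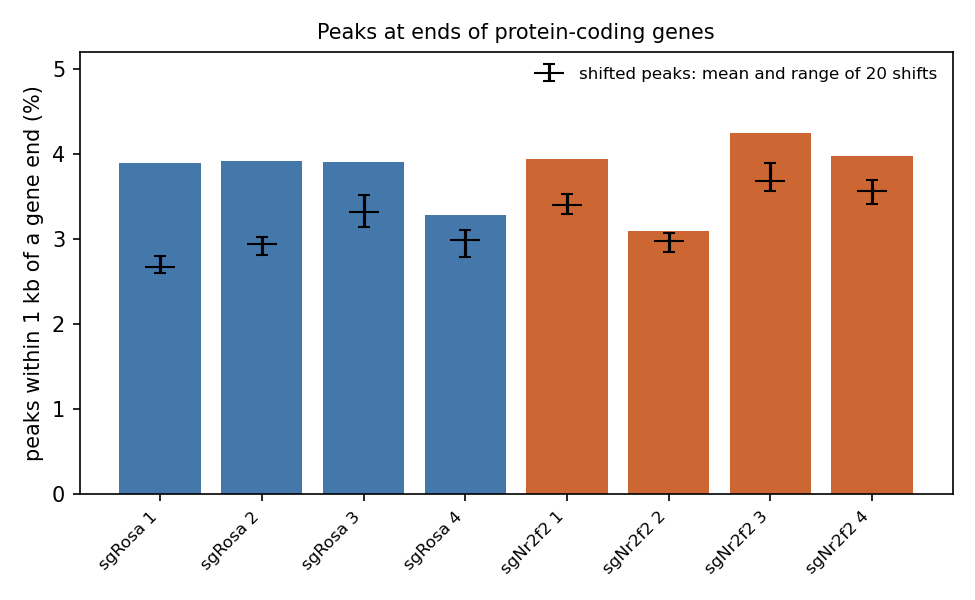
Bars give the percent of each library's 53864 strongest peaks with a summit within 1 kb of either end of a protein-coding gene. Black marks give the mean and range over 20 sideways moves of the same peaks; the bars stand above the marks in all 8 libraries, between 3.09% and 4.24%.

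The libraries had few regions in common. Merging the equal-length lists gave 405567 regions, of which 384772 were detected in 1 library and 230 in all 8. Of the strongest 300 peaks of a library, on average 64.7% overlapped one of the strongest 300 of another library, against 2.26% for the 53864 peaks. The Jaccard index by bases averaged 1.01% within sgRosa, 1.06% within sgNr2f2 and 1.03% between the groups. Between-group minus within-group similarity was -0.00904 percentage points, a separation that 0.257 of the 35 splits of the libraries reached (exact one-sided p = 0.257). The sign turned without sgNr2f2 2 (3.6e-04), sgNr2f2 3 (0.00533) and sgNr2f2 4 (2.3e-04).

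**Figure D3:**
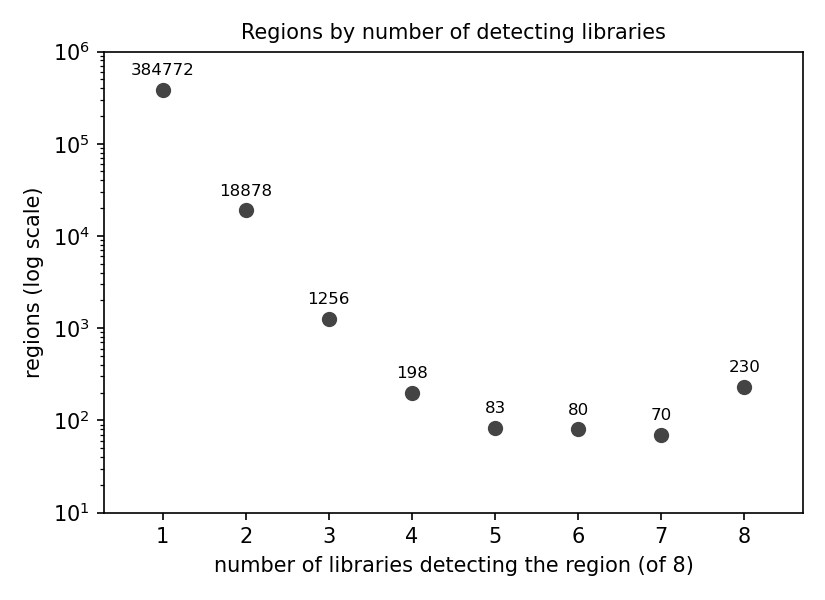
Points give the number of merged regions (log scale) detected in 1 to 8 of the 8 libraries. The count fell from 384772 in 1 library to 70 in 7 libraries and stood at 230 in all 8.

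The regions detected everywhere began with the same positions in every library, named here after their values were seen. Repeats and sites of excess signal had not been excluded here, so these positions are not shown to be open chromatin of neurons. The strongest peak of all 8 libraries lay on chromosome 9 at 35305146 to 35305661, inside the long non-coding RNA gene Gm33838, with a deposited −log10 p between 3703 and 4604. The next ranks were held in every library by chromosome 2 at 98666179 to 98667378, chromosome 9 at 24541946 to 24542229 and chromosome X at 143482937 to 143483179, each over 5 kb from any gene in the table. Among the 12 strongest shared regions, chromosome 6 at 103648999 to 103649362 was inside Chl1, which encodes a neural cell adhesion molecule. Chromosome 4 at 70378059 to 70378324 was inside Cdk5rap2, which encodes a centrosome protein. Of the 230 regions, 77 were inside protein-coding genes, 95 lay over 5 kb from any gene and 9 were within 1 kb of the end of a protein-coding gene. The 77 included several each in Sfi1, Tmem267 and Zfp978, so they do not count separate genes. Other regions also lay close together, such as a run on chromosome 9 between 2999936 and 3038289.

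The next comparison asked which regions were found in every library of 1 group and in none of the other. There were 4 regions in sgNr2f2 only and 4 in sgRosa only. The sgNr2f2 regions were all over 5 kb from any gene. They lay on chromosome 5 at 46142048 to 46142210, nearest to Lcorl (284296 bp away), and chromosome 1 at 145955681 to 145956239, nearest to Brinp3 (539852 bp). The others lay on chromosome 2 at 3964436 to 3964661, nearest to Frmd4a (53073 bp), and chromosome 3 at 103373503 to 103373887, nearest to Trim33 (14911 bp). The sgRosa regions were chromosome 17 at 20945193 to 20945707, over the end of Ppp2r1a, which encodes the scaffold subunit of protein phosphatase 2A, and chromosome 10 at 3257147 to 3257552, inside H60c. The remaining ones were chromosome 7 at 108030249 to 108030439, within 5 kb of the olfactory receptor gene Olfr478, and chromosome 4 at 147452716 to 147453099, inside the zinc finger gene Zfp982. Their deposited −log10 p ranged from 3.20 to 9.33. No region can pass a correction here, since 4 of 4 against 0 of 4 has an exact p of 0.0286. The sgNr2f2 count was 28, 29, 19 and 36 without sgNr2f2 1 to 4 in turn, and 7 without sgRosa 1, 3 or 4; the sgRosa count was 23, 23, 18 and 32 without sgRosa 1 to 4 in turn, and 7 without sgNr2f2 3.

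The same comparison was made at gene ends. Kif3c, which encodes a kinesin motor protein, and the zinc finger gene Zfp879 had a peak within 1 kb of an end in all 4 sgNr2f2 libraries and no sgRosa library. Ppp2r1a, Olfr478, Znrd1as, the proteasome subunit gene Psmb4 and the chaperone gene Hsp90ab1 had one in all 4 sgRosa libraries and no sgNr2f2 library. As only 2 genes were exclusive to sgNr2f2, genes found in 4 libraries against 1, or in 3 against 0, were also named by the same order. In 3 sgNr2f2 libraries against 0 these were Slc36a3, Armc6, Fez1, Zfp110, Mst1r, Aptx and Polr1a, and in 4 against 1 it was Clcn4, a chloride transporter gene. Such genes numbered 65 for sgNr2f2 and 94 for sgRosa, and the other splits of the libraries gave 38 to 100. With a 2 kb window the direction turned, with more exclusive gene ends in sgNr2f2 than in sgRosa, as given below. By contrast, the counts that follow use the 1 kb window. The sgNr2f2 count was 18, 21, 14 and 23 without sgNr2f2 1 to 4 in turn, and 4 without sgRosa 4; the sgRosa count was 19, 20, 29 and 39 without sgRosa 1 to 4 in turn, and 8 without sgNr2f2 1.

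Among the 230 regions detected in all 8 libraries, limma on rank normal scores placed 0 regions higher and 0 lower in sgNr2f2 at an adjusted p under 0.05. These regions were not filtered for repeats or sites of excess signal. Their ranks therefore do not show whether accessibility differed at other regions. At an unadjusted p under 0.05 there were 14, where chance gives 11.5, and the smallest adjusted p was 0.213. That region was on chromosome 5 at 137152678 to 137153025, inside the mucin gene Muc3, and was picked after its values were seen. Its mean rank percentile among the shared regions was 21.0 ± 4.29 in sgNr2f2 and 4.02 ± 1.68 in sgRosa (SD, n = 4 each). Its normal score was 0.961 higher in sgNr2f2 (SE 0.2), with a limma adjusted p of 0.213, and limma without the trend gave an adjusted p of 0.0193. Another shared region inside Muc3, at 137152154 to 137152548, had mean percentiles of 46.3 in sgNr2f2 and 43.4 in sgRosa. Its normal score differed by 0.0745 (limma adjusted p = 0.948). Without sgNr2f2 4, 1 region passed in the lower direction in sgNr2f2 (limma adjusted p = 0.047). It lay on chromosome 2 at 98662172 to 98663030, over 5 kb from any gene and 1031138 bp from Lrrc4c, the nearest. With all 8 libraries its mean rank percentile was 97.8 in sgNr2f2 and 98.3 in sgRosa. Under the other alternatives limma called no region.

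Gene lists fixed before the data were examined were compared by the number of peaks in or within 5 kb of their genes. All 373 listed entries were found in the gene table. None of the 24 lists passed Benjamini-Hochberg adjustment over the lists, and 1 had an unadjusted p under 0.05. The smallest p that 4 against 4 libraries allow is 0.0286, so at least 14 lists would have to reach it for any to pass.

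For single genes only the smallest exact p, 0.0286, lies under 0.05. Chance therefore gives fewer of the 365 listed genes than the 18.25 of a 0.05 rate. Of the 365, 2 had an exact p under 0.05, and none passed adjustment. These were the glutamate receptor genes Grin2b, with 8.25 ± 0.957 peaks in sgNr2f2 and 17.25 ± 5.91 in sgRosa, and Grm8, with 14 ± 6.68 and 28.25 ± 4.03 (SD, n = 4 each; exact p = 0.0286, adjusted p = 1 for both), named after their values were seen.

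For the neuronal identity lists, peaks at the 11 GABAergic neuron markers averaged 24.75 ± 7.68 per library in sgNr2f2 and 39.5 ± 5.2 in sgRosa (SD, n = 4 each; exact p = 0.0571, adjusted p = 0.514). The exact p was 0.0286 without sgNr2f2 4, in the full lists and with lists of 26932 peaks. This difference lay in Erbb4, which encodes a neuregulin receptor tyrosine kinase and was picked after its values were seen, with 16.75 ± 10.4 peaks in sgNr2f2 and 34 ± 3.74 in sgRosa (exact p = 0.0571). The other 10 markers together had 8 ± 4.16 and 5.5 ± 2.52 peaks (exact p = 0.429), the opposite direction. Of the 11 markers, 5 were detected in more sgNr2f2 libraries, 0 in more sgRosa libraries and 6 in equally many. Examples were Dlx1, Dlx6 and Slc32a1, the vesicular GABA transporter gene, each with a peak in 2 sgNr2f2 libraries and 0 sgRosa libraries. Glutamatergic neuron markers had 16 ± 6.73 peaks in sgNr2f2 and 19 ± 4.97 in sgRosa (exact p = 0.543, n = 4 each). Camk2a and Slc17a6, a vesicular glutamate transporter gene, were detected in 2 sgNr2f2 and 4 sgRosa libraries, and the forebrain transcription factor genes Emx1 and Fezf2 in 2 and 0. Interneuron markers had 35.25 ± 4.03 and 36 ± 7.75 peaks (exact p = 0.914, n = 4 each), with the serotonin receptor gene Htr3a in 3 sgNr2f2 and 0 sgRosa libraries. Amygdala nucleus markers had 35.25 ± 11.2 and 50 ± 11.6 peaks (exact p = 0.171, n = 4 each), with Prkcd, a marker of the lateral central amygdala, in 4 and 2 libraries.

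For the cells that neuron isolation is meant to remove, astrocyte markers had 22 ± 4.24 peaks in sgNr2f2 and 14 ± 2.94 in sgRosa (SD, n = 4 each; exact p = 0.0286, adjusted p = 0.514). This unadjusted p is the smallest the design can give, and it was 0.0857 without sgRosa 1 and 0.0571 without sgNr2f2 1. It was also 0.4 with lists of 26932 peaks, 0.514 by the nearest gene end and 0.143 without Slc1a2, a glutamate transporter gene that held the most peaks of the list and was picked after its values were seen, and stayed at 0.0286 in the full lists and in the order by fold enrichment. Gjb6, which encodes connexin 30, was detected in 3 sgNr2f2 and 0 sgRosa libraries, Aqp4, the water channel of astrocyte endfeet, in 1 and 3, and Gfap in 4 and 2. Of the 12 astrocyte markers, 3 were detected in more sgNr2f2 libraries, 4 in more sgRosa libraries and 5 in equally many. Markers in more sgNr2f2 and in more sgRosa libraries numbered 8 and 1 for the ependymal list, 7 and 2 for microglia and 6 and 2 for vascular cells. They numbered 3 and 4 for oligodendrocytes and 4 and 4 for their precursors. Ependymal and choroid plexus markers had 8.75 ± 3.59 and 5.5 ± 0.577 peaks (exact p = 0.0857, n = 4 each; 0.0286 without sgNr2f2 1 and in the full lists) and microglia markers 13.5 ± 2.52 and 10.25 ± 3.30 (exact p = 0.2, n = 4 each). The complement gene C1qa was detected in 3 sgNr2f2 and 0 sgRosa libraries, and Itgam in 4 and 1. Vascular markers had 19.75 ± 4.57 and 16.75 ± 3.95 peaks (exact p = 0.429, n = 4 each), oligodendrocyte markers 11.5 ± 4.80 and 11.25 ± 4.11 (exact p = 1, n = 4 each), and oligodendrocyte precursor markers 21 ± 10.1 and 19.5 ± 4.65 (exact p = 0.857, n = 4 each). The summed share of peaks at these 6 lists was 0.179 ± 0.036% in sgNr2f2 and 0.143 ± 0.00927% in sgRosa (SD, n = 4 each; exact p = 0.0857). Divided by the share expected from the density within 1 Mb, a comparison chosen after the data were seen, it was 1.10 ± 0.222 and 1.03 ± 0.0533 (SD, n = 4 each; exact p = 0.571).

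No list tied to neuronal activity, stress or metabolism had an unadjusted p under 0.05. Immediate early genes had 11 ± 2.45 peaks in sgNr2f2 and 11.5 ± 4.80 in sgRosa (exact p = 0.886, n = 4 each), with Npas4, an activity-induced transcription factor gene, detected in 4 sgNr2f2 and 1 sgRosa libraries and Egr3 in 1 and 3. Glucocorticoid and stress-hormone genes had 37 ± 9.87 and 30 ± 8.68 peaks (exact p = 0.343, n = 4 each), and 11 of 14 members were detected in equally many libraries of each group. Neuropeptide genes had 7.75 ± 1.26 and 5.75 ± 0.957 peaks (exact p = 0.0857, n = 4 each), with Cck in 2 sgNr2f2 and 0 sgRosa libraries and Gal in 1 and 3. Oxidative phosphorylation and mitochondrial biogenesis genes had 32 ± 4.83 and 30.75 ± 8.54 peaks (exact p = 0.886, n = 4 each), with Uqcrc1, which encodes a respiratory chain subunit, in 3 and 0 libraries, Atp5b in 1 and 3 and Sdha in 2 and 4. Of the 20 members, 6 were detected in more sgNr2f2 and 7 in more sgRosa libraries. Interferon response genes had 11 ± 4.83 and 8.75 ± 4.27 peaks (exact p = 0.486, n = 4 each), and genes of the p53 and DNA damage response 5 ± 1.41 and 5.75 ± 2.75 (exact p = 0.743, n = 4 each). Housekeeping genes had 5.5 ± 2.08 and 5 ± 1.83 peaks (exact p = 0.857, n = 4 each).

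The synaptic adhesion and scaffold, axon guidance, voltage-gated ion channel and glutamate receptor lists held the most peaks. Their genes also spanned the most sequence, from 5933 to 10836 kb per list, against 134 kb for the housekeeping list. Divided by the share expected from the density within 1 Mb, their group means were 0.969 to 1.19. Synaptic adhesion and scaffold genes had 247 ± 31.0 peaks per library in sgNr2f2 and 275 ± 46.9 in sgRosa (exact p = 0.429, n = 4 each), and axon guidance genes 218 ± 30.8 and 234 ± 16.4 (exact p = 0.429, n = 4 each), with the netrin receptor gene Dcc at 25.75 and 27 peaks. Voltage-gated ion channel genes had 166 ± 30.3 and 154 ± 13.1 (exact p = 0.571, n = 4 each), with the potassium channel gene Kcna2 in 4 sgNr2f2 and 1 sgRosa libraries and the sodium channel gene Scn8a in 2 and 4. Glutamate receptor genes had 156 ± 12.8 and 170 ± 15.4 (exact p = 0.257, n = 4 each), GABA receptor and inhibitory synapse genes 73.75 ± 15.7 and 86 ± 6.73 (exact p = 0.2, n = 4 each; 0.0286 without sgNr2f2 2), and synaptic vesicle release genes 57 ± 11.5 and 63 ± 7.07 (exact p = 0.457, n = 4 each). Nuclear receptor genes, a list that holds Nr2f2 itself, had 91.5 ± 22.4 and 73 ± 14.3 peaks (exact p = 0.2, n = 4 each). Only 3 lists held any of the 230 shared regions, with 1 region each, and none differed in rank (smallest adjusted p = 0.6 by exact permutation).

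**Figure D4:**
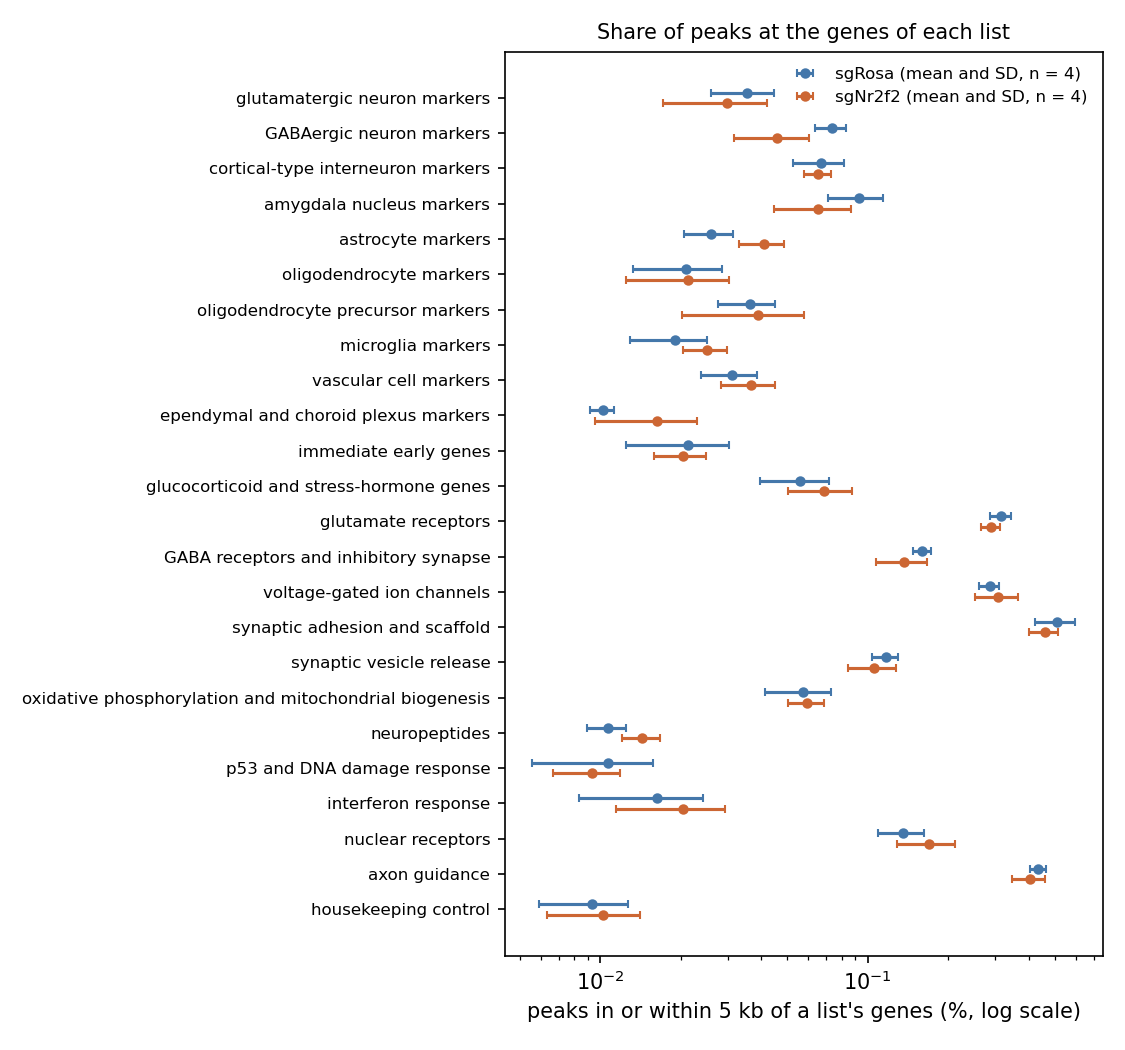
For each gene list, points give the mean percent of a library's 53864 strongest peaks that lay in or within 5 kb of the list's genes (log scale), with bars of 1 SD over 4 libraries per group. Astrocyte markers, at 0.0408% in sgNr2f2 and 0.026% in sgRosa, had the only unadjusted p under 0.05, and no list passed the adjustment.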

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

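The tests of the threshold step, of depth and of the knockdown, and those of the gene table and of weak peaks at gene ends, were chosen after the results were seen. For spread fragments the bounds were set beforehand, but the sideways move that this test uses was chosen after the data were seen. In each group of 4 libraries, 36 measures were searched for a library far from the other 3 by Dixon's ratio. This singled out 9 of 72 groups, where chance gives about 1 in 20, or 3.6. The measures overlap, such as number of peaks and covered length, and a count that differs from tied counts is always flagged. The comparison of 9 with 3.6 is therefore not a test.

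sgRosa 4 stood apart in 5 measures. It had 143405 peaks against 60880 to 63648 in the other sgRosa libraries, and its peaks covered 26.7 Mb against 11.36 to 11.96 Mb. Its median fold enrichment was 2.72 against 2.61 to 2.63, its share of peaks at gene ends 3.28% against 3.89% to 3.91%, and it had 896 peaks on the X chromosome against 53 to 76. In sgNr2f2 3, 312 peaks had a −log10 q of at least 5, against 252 to 259 in the rest of its group. Within 50 kb of Nr2f2, sgRosa 3 had 7 peaks against 1 to 2, and sgNr2f2 3 had 1 peak against 2 in each other sgNr2f2 library. The share of peaks at glucocorticoid and stress-hormone genes was 0.0798% in sgRosa 3, against 0.0464% to 0.0483% in the other sgRosa libraries.

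The number of peaks ranged from 53864 to 143405. Greater depth would give more peaks at a higher background, but the rank correlation of the number with the recovered background was -0.405. The range within sgRosa alone was 28.3 times the difference between the group means, but 0.159 times without sgRosa 4, so an effect of the Nr2f2 knockdown stays open. Another candidate explanation is the whole-number step of the peak threshold. The number followed the chance that background exceeds the smallest passing pileup, with a rho of 0.786. That pileup was found from the peaks themselves, so this is a hypothesis formed and tested on the same lists.

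Few peaks lay at gene ends: the observed share was 1.04 to 1.46 times that of peaks moved sideways. A gene table of another build would leave no excess, yet 8 of 8 libraries exceeded every moved share, and a loss through the Nr2f2 knockdown over all peaks goes against a ratio of only 1.27 in sgRosa. After the strongest 300 peaks, down to rank 3000, the ratio was 1.60 ± 0.461 in sgRosa and 1.107 ± 0.0646 in sgNr2f2 (SD, n = 4 each; exact p = 0.114), so for these stronger peaks an effect of the knockdown stays open. Weak peaks at low depth would leave the stronger peaks at gene ends, but the same peaks had a median ratio of 1.15; in sgRosa 1 and sgRosa 2 the ratios were 1.97 and 1.98, so for these libraries that explanation stays open. Fragments spread along the genome may also contribute: outside the strongest 1000 peaks, lists overlapped 2.21 times as much as moved lists (range 1.74 to 2.74), which lies between the values set beforehand for and against it.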

How the results depend on the processing

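The analysis without sgRosa 4 and sgNr2f2 2 together, the density-corrected list shares, the lists without their member with the most peaks and the leave-one-out background correlations were chosen after seeing the data; the other alternatives were planned. For number, covered length, width, gene-end share, similarity and the Nr2f2 locus, 0 of 66 alternative values had an exact p under 0.05 (smallest 0.143). Another 12, blocked or from 3 against 3 libraries, could not reach it. Among the 66, the Nr2f2 locus with −log10 q of at least 5 held no peak in any library and could not reach it either. Without sgRosa 4 and sgNr2f2 2 the gene-end share had an exact p of 0.1, the smallest 3 against 3 allow. These 2 libraries had the lowest share of their groups. In the remaining libraries the share was higher in sgNr2f2, at 3.93% to 4.24% against 3.89% to 3.91% in sgRosa. Relative to peaks moved sideways the direction was opposite, with ratios of 1.12 to 1.16 in sgNr2f2 and 1.18 to 1.46 in sgRosa. With −log10 q of at least 5, the width difference was 7.25 bp, the gene-end share difference -0.628, the similarity difference -0.415, and exclusive regions and gene ends were 0 in both groups, with 220 to 312 peaks per library left. With lists of 26932 peaks, exclusive regions were 2 in sgNr2f2 and 1 in sgRosa, and exclusive gene ends 0 and 0. In full lists exclusive gene ends were 6 and 15. With 500 bp windows exclusive regions were 9 and 8, and 2 sgNr2f2 regions were absent from the full sgRosa lists. A 2 kb window gave a gene-end share difference of 0.553 and 20 and 11 exclusive gene ends. The Nr2f2 difference was -3.5 peaks with a 200 kb flank. Limma without trend called 1 shared region higher, with 16 at an unadjusted p under 0.05. Without sgRosa 4 and sgNr2f2 2 together, exclusive regions were 37 and 38 and exclusive gene ends 28 and 43. Fewer libraries admit more exclusive items by construction; for the other changes the cause was not tested.

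Leaving out each replicate gave 5 to 36 exclusive regions in sgNr2f2 and 5 to 32 in sgRosa, 2 to 23 and 5 to 39 exclusive gene ends, 0 to 1 shared regions lower in sgNr2f2, and a background correlation from -0.797 to -0.117. Of 312 list values under the alternatives, 287 kept their side of the unadjusted threshold and moved by under 1 SD. Another 5 no longer passed it, all for the astrocyte list, 6 newly passed it and 14 moved by over 1 SD. Turns of sign among them, such as those of the oligodendrocyte and precursor lists given below, are not counted separately. The 312 values leave out 24 blocked values, which could not pass, and 24 with −log10 q of at least 5, where 16 lists held no peak. No list passed adjustment under any alternative. Without the member with the most peaks, the difference turned sign in 6 of 24 lists, among them the GABAergic markers (0.00464 percentage points).

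As a replicate block, libraries with the same number gave an exact p of at least 0.125, the smallest possible, so no call could be made; the difference in number of peaks remained -2911, and blocked limma called 0 shared regions, with 15 at an unadjusted p under 0.05. Whether equal numbers mark a shared litter, batch or day is not known, and the libraries were treated as unpaired. Over 535 bins of 5 Mb, same-number correlations of deviations ran from -0.178 to 0.341, with 1 of 4 over 0.1. Of the sgRosa libraries, 1 of 4 correlated best with its own number. Correlations of this kind cannot exclude a shared batch. Motif comparisons were not run, as no genome sequence was used, and camera was not run, as no list held 2 shared regions. Without read totals depth is unknown, and a region missing from a list is not shown to be closed.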

Other observations

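The counts of splits for exclusive regions and for exclusive gene ends, the list shares divided by density, and the lists without the member with the most peaks, were chosen after the results were seen. For regional density the bounds were set beforehand, but the density within 1 Mb was itself chosen after the data were seen. The other tests here were chosen before.

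Markers of cells that neuron isolation should remove had more peaks in sgNr2f2 in 6 of 6 lists, and in 3 of 6 after division by the density within 1 Mb. The oligodendrocyte list turned to lower without sgRosa 2, sgNr2f2 1 or sgNr2f2 3, and the precursor list without sgNr2f2 1. Without Mbp, its member with the most peaks, the oligodendrocyte list also turned to lower (-0.00278 percentage points). Beyond the genes named above, the myelin regulator gene Myrf was detected in 3 sgNr2f2 and 1 sgRosa libraries, the endothelial cadherin gene Cdh5 in 4 and 2, and the cilia gene Rsph1 in 4 and 1. In the other direction, the glial transcription factor gene Sox10 was detected in 0 and 2 libraries, the endothelial transporter gene Slco1a4 in 2 and 4, and the precursor genes Cspg4 in 1 and 3 and Pdgfra in 2 and 4. The interferon-induced gene Ifit3 was detected in 3 and 0 libraries and Ifih1 in 1 and 4, and among genes of the p53 response Cdkn1a in 4 and 1 and Mdm2 in 0 and 2. The exact p of these single genes was at least 0.0857.

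Across the 24 lists, 13 had higher and 11 lower mean shares in sgNr2f2. A candidate explanation is that more glial and vascular cells remained in sgNr2f2, which would add peaks at the ends of their marker genes. Of 73 markers, 8 ± 2.94 had a gene-end peak in sgNr2f2 and 6 ± 2.16 in sgRosa (SD, n = 4 each), a difference of 2 with an exact p of 0.429, which leaves the explanation open. Regional density of peaks may also contribute: differences predicted from the density within 1 Mb had a rank correlation of 0.395 with those observed, against up to 0.583 in the other splits of the libraries. After dividing by that density the astrocyte markers had an exact p of 0.143 and the GABAergic markers 0.0286 (adjusted p 0.686), with Erbb4 included, and no list passed adjustment.

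Chance could not be excluded for the counts of lists, exclusive regions and exclusive gene ends. Of 35 splits of the 8 libraries, 16 gave at least as many lists with an unadjusted p under 0.05 as the real 1 (highest other split 3). For exclusive regions 10 splits reached the real 8 (highest other 12), and for exclusive gene ends 15 reached the real 7 (highest other 10). For limma, 35 of 35 splits called at least the real 0 regions (highest other 1); with a real count of 0 every split does so, and the count decides nothing.

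The X chromosome carried few peaks per Mb, between 0.0112 and 0.0906 of the autosomal density. The hypothesis tested was that the single X chromosome in males lowers the background there in proportion and so sets this density. The observed density was within 3-fold of that prediction in 2 of 8 libraries, and 2.23 to 5.35 times the prediction over the 8 libraries. The bound set beforehand took any density over 3-fold from the prediction as evidence against it. That bound was wrong for densities above the prediction, as in all 8 libraries, since the single X then predicts a larger deficit than was seen. The single X as the source of the deficit stays open, and what the prediction leaves over is a surplus of X peaks.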
